A study of Mus musculus with 30 samples.

How the data were processed

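The authors deposited 1 table of 626 probes by 30 samples. Per the labels, RNA was hybridised with a fluorescent barcode and a biotin moiety, tissue and cell RNA was extracted with one kit and exosome RNA with another, and RNA concentrations were adjusted to 30 to 40 ng/µl. The deposited values are signal values. Their low values, read directly, show what the authors did: counts had each sample's background taken off, were set to a floor of 1 and, for all probes but the positive and negative controls, were multiplied by 1 factor per sample. The factor, read from the spacing of the low values, ran from 0.6025 to 2.40, and 100% of the low values under 60 were whole multiples of it within 0.1 once the fraction left by the background was allowed for. The tool, the background rule and the basis of the factor are not given in the sources used here. The factor equalised neither the total signal nor the positive, ligation or mRNA controls. Because of the background subtraction the values are not counts, so no count test was used.

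The table holds 566 mouse miRNA probes, 33 viral miRNA probes (none over the detection limit in any sample), 6 positive, 8 negative and 6 ligation controls, 4 mouse mRNA probes and 3 probes of other species. Only mouse miRNA probes entered the tests. Of all probes 9 cover several miRNAs and are not split. The table gives names without genome positions, so no coordinates are given. Samples were put in groups from their titles. The letter in each sample's description differs between the 4 sample kinds (A for fat, C for aorta, B for cells, E for exosomes), so comparisons across kinds are confounded with it.

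The detection limit was the mean plus 2 SD of the 240 negative control values, 29.8. Negative controls were not multiplied by the authors' factor, while miRNA values were. The limit thus stands for more counts above background where the factor was low (0.6025 in HFD aorta replicate 2) than where it was high (2.40 in chow aorta replicate 1). Numbers of probes over the limit, the filter and lower bounds of folds carry this mismatch. A miRNA was tested when it lay over the limit in at least as many of the fitted samples as the smaller group holds. Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on log2(value + 1) with Benjamini-Hochberg adjustment over the miRNAs tested, and calls at an adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low miRNAs. Each treatment comparison and the comparison of MAT with culture was fitted on its own 2 groups. The comparisons between tissues, between exosomes and cells, and of differences of effects were fitted on the 4 groups concerned. Where no sample of 1 group was over the limit, the fold is a lower bound, from the brighter group's mean log2 value less the dimmer group's mean with each value set to at least 29.8. Means are given with their SD and differences of differences with their standard error. The depth behind each value is limited by the counts above background, from 1663 in the poorest exosome sample to 496456 in the richest MAT sample.

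Before the data were examined 24 lists of miRNAs were written down. Lists with at least 3 tested members were tested with camera of limma at a preset correlation of 0.01, and again with an estimated correlation. The miRNAs named were chosen by a rule fixed at the same time: up to 10 higher and 10 lower by size among those past the threshold, the 5 smallest p where fewer than 5 passed, up to 4 members of each list that passed, and fixed markers of LPS response, diet and cell identity. The following were named outside the rule after their values were seen: miR-222 in culture, and miR-146a, miR-150 and miR-451 in the MAT diet comparison. So were the most abundant miRNAs of each sample kind.

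The replicate numbers of the labels were checked for pairing by correlating the deviations of same-numbered samples from their group means. In cultured adipocytes all 4 pairs correlated at 0.50 to 0.88, which pairs them, so the blocked result is printed beside the main one. In no other comparison did every same-numbered pair correlate over 0.1. Same-numbered aorta and fat correlated at 0.16 to 0.33 after HFD and at -0.14 to 0.0068 on chow, and a block that joins them was added as an alternative. Alternatives were a pseudocount of 16, no filter, a doubled limit, centring, quantile and top-100 scaling, trended and robust moderation, sample weights, all 30 samples in 1 fit, the replicate block, leaving out each sample and a threshold of 0.10. Undoing the authors' factor, scaling to the positive controls, setting values under the limit to the limit, the block across sample kinds and leaving out doubted samples were added after seeing the data. Setting values to the limit also narrows the spread of low miRNAs. The mRNA probes were compared with exact permutation tests.

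The procedure was tested on simulated data. The real means were used, with the real spreads shuffled across miRNAs. Values were drawn as independent and normal, without the floor of 1 or shifts shared by a sample, so real rates may differ. Changes of 2 on the log2 scale were recovered in 92.5% of cases for MAT diet (157 miRNAs) and 79.6% for AA diet (99). For adipocyte LPS the share was 87.4% (98) and for exosome LPS 10% (26). Changes of 1 were recovered in 60.6%, 46.2%, 46.8% and 0.667%. Figures were drawn with matplotlib.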

Results

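Mouse miRNA levels were measured in 30 samples from 8 groups. Male C57BL6 mice, an inbred laboratory strain, received normal chow (NCD) or a high-fat diet with 60% fat (HFD) from 4 to 20 weeks of age. Mesenteric adipose tissue (MAT), the fat around the intestine, was taken from 5 samples per diet, and abdominal aorta (AA) from 3 per diet. Pre-adipocytes from the stromal fraction of mesenteric fat were differentiated to adipocytes in culture (MAT-Ad) and given PBS or 1 µg/ml lipopolysaccharide (LPS), a bacterial wall component that sets off inflammatory signalling, for 24 h, with 4 samples per treatment. Exosomes, small vesicles released by cells, were collected from the culture medium (MAT-Ad-EX), with 3 samples per treatment. The labels number the samples of each group but do not say which came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical.

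Total miRNA signal differed most between sample kinds. It ranged from 270569 to 496704 in the 10 MAT samples, from 174770 to 287152 in the 6 AA samples and from 70149 to 142968 in the 8 cultured adipocyte samples. PBS exosomes gave only 1796 to 2861 and LPS exosomes 5753 to 33349. Of 566 mouse miRNA probes, 142 to 172 lay over the detection limit of 29.8 in MAT, 90 to 116 in AA and 82 to 111 in cultured adipocytes. In PBS exosomes 7 to 14 did, and in LPS exosomes 31 to 67. The precision of the exosome values is limited accordingly. In PBS exosome replicate 1 the ligation control LIG_POS_A, an artificial RNA that reports the step that joins a tag to each miRNA, read 126, against 2832 to 23141 in the other 5 exosome samples. In chow aorta replicate 1 it read 50714, against 4295 to 8159 in the other 5 aortas. Correlations of log2 values between replicates ran from 0.53 to 0.87 in PBS exosomes and from 0.65 to 0.81 in LPS exosomes. No pair of samples held identical values.

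**Figure D1:**
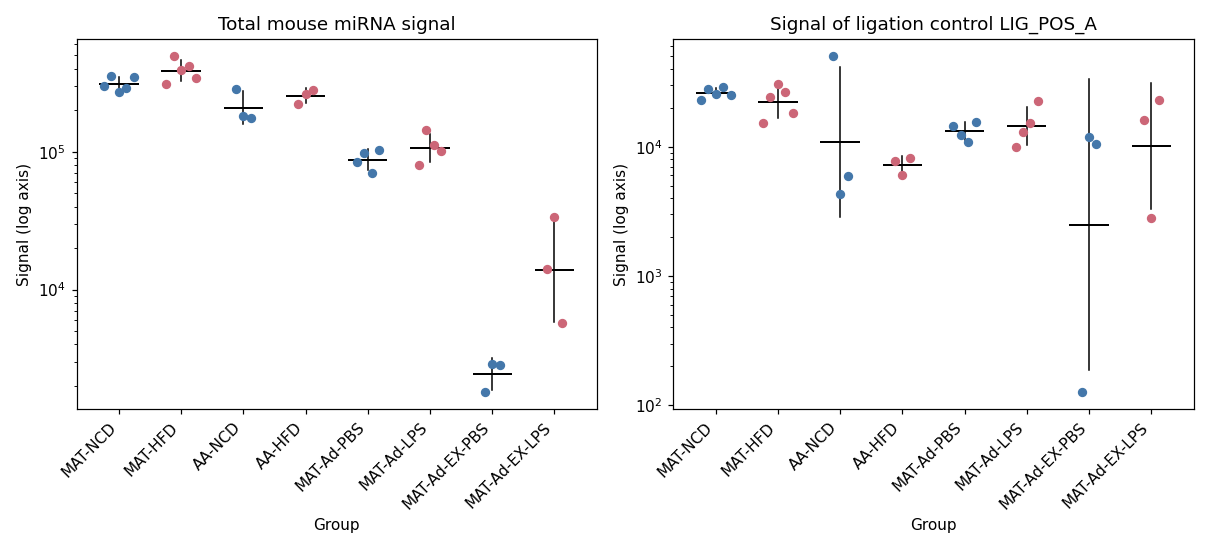
Total mouse miRNA signal (left) and the ligation control LIG_POS_A (right) on log axes for each of the 30 samples; points are samples, horizontal bars geometric means and vertical bars 1 SD of the log values. PBS exosomes lie at 1796 to 2861 in total signal, and PBS exosome replicate 1 has a ligation control of 126.

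The first comparison asked which miRNAs of mesenteric fat differ with diet. The paralogues miR-221 and miR-222, which share a seed sequence and restrain several cell-cycle inhibitors, and both arms of miR-335, which lies within the imprinted gene Mest, rose after HFD with the 4 smallest p. miR-335-5p went from a signal of 184 ± 118 to 1855 ± 359 (SD, n = 5 each), an 11.8-fold rise. miR-221 went from 30.6 ± 16.3, with 2 of 5 chow samples below the detection limit, to 371 ± 92.8, which is 9.84-fold with these 2 set to the limit. miR-222 and miR-335-3p were below the detection limit in all 5 chow samples and over it in all 5 HFD samples, at means of 67.3 and 61.6, so they rose at least 2.09-fold and at least 2.02-fold. Every HFD sample lay above every chow sample for these 4 miRNAs, with limma adjusted p between 2.5e-06 and 5.6e-05.

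Of 157 miRNAs tested in MAT, 24 passed at an adjusted p under 0.05, 23 higher and 1 lower. miR-210, a miRNA induced by low oxygen, was the one that fell, from 62.4 ± 11.4 to 30.4 ± 13.3. With the 3 of 5 HFD samples below the limit set to it, the fall was 1.75-fold. Of the miRNAs linked to adipose tissue in obesity, 13 of the 23 tested rose and none fell, with 13 passing when adjusted over the list alone. Among them miR-342-3p rose from 2582 ± 1144 to 5684 ± 1363, miR-21 from 4100 ± 1747 to 8077 ± 1582, and miR-34a, a p53 target, from 78.7 ± 45.7 to 168 ± 8.84. Of the LPS and NF-kB responsive list, 6 of 14 rose (7 adjusted over the list alone), including miR-146b at 40.3 ± 20.9 against 111 ± 27.9 and the myeloid miR-223 at 1384 ± 161 against 2349 ± 436. With the 2 of 5 chow samples of miR-146b below the limit set to it, its rise was 2.61-fold. miR-146a of the same list had similar means, 1827 ± 765 and 1941 ± 775. From the Dlk1-Dio3 cluster, an imprinted region with many miRNAs, 4 of 15 rose (8 adjusted over the list alone). These were miR-411, from 13.9 ± 13.5 to 63.7 ± 32.3, miR-495, miR-382 and miR-329. With the 4 of 5 chow samples of miR-411 below the limit set to it, its rise was 1.89-fold. Of the miRNAs lowered during or opposing adipocyte differentiation, 3 of 11 rose (3 adjusted over the list alone), namely miR-221, miR-222 and miR-27a, a repressor of adipogenesis, which went from 2973 ± 435 to 5402 ± 1039. In the Sfmbt2 cluster none of the 5 tested passed singly, and none when adjusted over the list alone. Its miR-466g had means of 210 ± 45.3 and 141 ± 52.8.

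**Figure D2:**
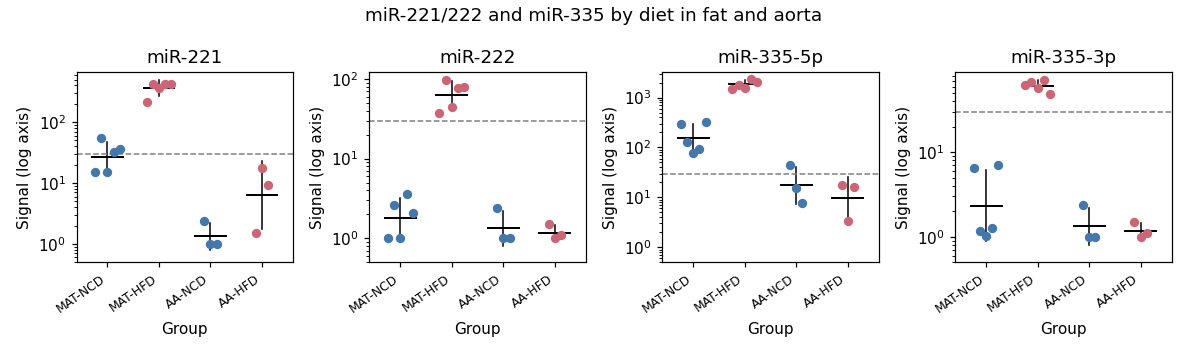
Signal (log axis) of miR-221, miR-222, miR-335-5p and miR-335-3p in MAT and aorta by diet; points are samples, horizontal bars geometric means, vertical bars 1 SD of the log values and the dashed line the detection limit of 29.8. For all 4, the 5 MAT samples after HFD lie above the 5 on chow, while miR-222 and miR-335-3p lie below the limit in all 6 aortas.

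In the set test these 5 of 18 lists passed, the first 4 upward and the Sfmbt2 cluster downward relative to other miRNAs, with camera adjusted p of 0.0099 for the LPS list and 0.040 for each of the others. With an estimated correlation none passed, the lowest adjusted p being 0.76. Markers of blood moved unevenly: miR-451, abundant in red blood cells, was 57354 in HFD replicate 2 against 2710 to 7622 in the other 9 MAT samples, and the lymphocyte miR-150 had means of 11222 ± 5871 on chow and 8714 ± 8457 on HFD (adjusted p = 0.51). The leukocyte miR-142-3p had means of 4270 ± 3109 and 2000 ± 1708 (adjusted p = 0.49).

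The count in MAT depended on single samples: it was 48 without HFD replicate 1, 8 without chow replicate 3 or 4, 9 without chow replicate 1 or HFD replicate 2, 10 without HFD replicate 4 and 14 without HFD replicate 5, while miR-221, miR-222, both miR-335 arms and miR-652 passed in all 10 such runs. Among these 10 runs miR-146b lost its call only without chow replicate 3 (adjusted p = 0.054). miR-411, miR-495, miR-382, miR-329, miR-342-3p, miR-34a, miR-21, miR-223, miR-27a and miR-210 passed in 2 to 5 of the 10, and each failed without chow replicate 1, 3 or 4 or HFD replicate 2, with adjusted p of 0.051 to 0.12. The median log2 difference over all tested miRNAs was 0.31, and centring each sample on its median gave 18 higher and 5 lower, quantile normalization 13 and 5, and scaling to the 100 most abundant miRNAs 14 and 6. Under these 3 scalings miR-223, miR-342-3p and miR-34a lost the call each time, miR-329 after quantile normalization and top-100 scaling, miR-27a after quantile normalization and miR-411 after top-100 scaling, with adjusted p of 0.051 to 0.098, while all stayed higher after HFD. Scaling to the positive controls ended the call of miR-210 (adjusted p = 0.058). Over 14 settings other than runs without 1 sample, miR-146b kept its call in 12 (highest limma adjusted p = 0.15) and miR-27a in 11 (0.63). The count was 10 for miR-21 (0.27), 8 for miR-342-3p (0.29) and 8 for miR-223 (0.64). miR-221, miR-335-5p and miR-652 kept it in all 14, and miR-222 and miR-335-3p in all 13 that tested them.

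In the aorta the same diets gave no miRNA past the threshold among 99 tested with limma. At an unadjusted p under 0.05 there were 11. The miRNAs with the smallest p included miR-378, encoded in the metabolic coactivator gene Ppargc1b, with 205 ± 72.3 on chow and 393 ± 41.8 on HFD (n = 3 each), and miR-132, with 73.8 ± 14.6 and 130 ± 16.6. Both had an adjusted p of 0.40. The whole profile leaned the same way, with 79.8% of the 99 miRNAs higher after HFD and a median log2 difference of 0.24. Members of the let-7 family, conserved miRNAs abundant in differentiated cells, had higher means after HFD in all 9 cases, such as let-7g at 4118 ± 284 and 6137 ± 674, but none passed singly or when adjusted over the list alone. The family passed the set test upward (camera adjusted p = 0.020), and not with an estimated correlation (adjusted p = 0.99) or after centring on the median. Without chow replicate 1, the aorta with the high ligation control, 1 miRNA passed.

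Whether the diet effect differed between aorta and fat was tested directly. Of 175 miRNAs, 3 passed, namely miR-222, miR-335-3p and miR-335-5p, with adjusted p of 3.7e-05, 0.00061 and 0.0092. All 3 had risen in fat. In aorta miR-222 and miR-335-3p were below the detection limit in all 6 samples, and miR-335-5p was over it in 1, with means of 22.3 ± 18.7 and 12.3 ± 7.89. The diet effect in aorta could therefore not be measured for them, and their passing restates the rise in fat. miR-221, also below the limit in all 6 aortas, did not pass (adjusted p = 0.39). The obesity-linked list (3 of 24 members passing singly, 4 adjusted over the list alone) and the LPS and NF-kB list (1 of 14, and 1 adjusted over the list alone) went lower in aorta relative to fat in the set test, with camera adjusted p of 0.0050 and 0.0053, and the Sfmbt2 cluster (none of 5, and 1 adjusted over the list alone) went higher, with 0.047. With an estimated correlation these adjusted p were each 0.71. The count was 7 without chow aorta replicate 1 and 5 without chow aorta replicate 2, and centring on the median or scaling to the top 100 gave 3 lower and 1 higher.

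The aorta was set beside mesenteric fat on chow to describe what sets the tissues apart. miR-140, a miRNA best known from cartilage, was 10.5-fold higher in aorta (2110 ± 609, n = 3, against 202 ± 59.3, n = 5; adjusted p = 1.9e-07). Several markers of blood cells and endothelium were lower there, as were 125 of the 128 miRNAs that differed: the leukocyte miR-142-3p was 20.1 ± 20.8 against 4270 ± 3109, miR-150 was 163 ± 52.0 against 11222 ± 5871, miR-223 was 118 ± 37.8 against 1384 ± 161, and the endothelial miR-126-3p was 2932 ± 369 against 18153 ± 3217. The smooth muscle miRNAs miR-143 and miR-145 were abundant in both, miR-145 at 63868 ± 24698 and 37808 ± 20123 (adjusted p = 0.18), and miR-143 did not pass either (adjusted p = 0.38). Both passed as higher in aorta after centring on the median or top-100 scaling, and miR-143 also after quantile normalization. As a share of the miRNA signal miR-145 was 29.3% ± 2.48 in aorta and 11.9% ± 5.39 in fat. miR-451 was 1095 ± 492 against 4883 ± 1907 (adjusted p = 0.016), a call lost without chow aorta replicate 2 (adjusted p = 0.069) or 3 (0.054). miR-139-5p and miR-708 were below the limit in all chow aortas and at least 7.04-fold and at least 3.80-fold lower.

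Of 175 miRNAs, 128 differed between the tissues, 3 higher and 125 lower in aorta, and none of 19 lists passed the set test (lowest adjusted p = 0.18). The split depends on the scaling: centring on the median, which evens it out by construction, gave 53 higher and 54 lower, quantile normalization 49 and 39, and top-100 scaling 47 and 65, and miR-27a and miR-199a-3p, the other miRNAs called higher in aorta, kept the call in 12 of 15 other settings each and miR-140 in all 15. Tissue also goes with the letter in the sample descriptions, so tissue and whatever the letter stands for cannot be told apart.

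The next comparison asked which miRNAs of cultured adipocytes respond to LPS. miR-146a, an NF-kB target that dampens Toll-like receptor signalling, rose from 95.4 ± 34.2 to 743 ± 260 (SD, n = 4 each), 7.69-fold (limma adjusted p = 0.0010). miR-221 was below the detection limit in all 4 PBS samples, at 6.57 ± 4.47, and over it in all 4 LPS samples, at 105 ± 61.3, at least 3.02-fold higher (adjusted p = 0.0034, and 0.077 without the filter on low miRNAs). Its paralogue miR-222 stayed at the floor in all 8 samples, as did miR-155 and miR-147, both known LPS-induced miRNAs of macrophages. miR-21 had means of 2410 ± 685 and 4315 ± 1551 (adjusted p = 0.37), and miR-132 of 338 ± 68.7 and 436 ± 147 (adjusted p = 0.64). miR-350 had 50.8 ± 14.0 and 111 ± 24.4 (adjusted p = 0.097).

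These were the only 2 of 98 miRNAs to pass, both higher, with 11 at an unadjusted p under 0.05. Of the LPS and NF-kB list 2 of 9 rose (2 adjusted over the list alone), and none of 15 lists passed the set test (lowest adjusted p = 0.32). Same-numbered PBS and LPS samples deviated together, and with the number as a block 8 passed, 7 higher, among them miR-26b, miR-350 and the probe shared by miR-20a and miR-20b. This fit gave all miRNAs 1 common spread. With the block the LPS and NF-kB list passed upward (camera adjusted p = 0.025; 0.91 with an estimated correlation). Centring on the median gave 4 higher and 1 lower, quantile normalization 3 and 1, and top-100 scaling 2 and 1; without LPS replicate 1, 4 passed, and with the detection limit doubled miR-221 was no longer tested and miR-146a alone passed.

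**Figure D3:**
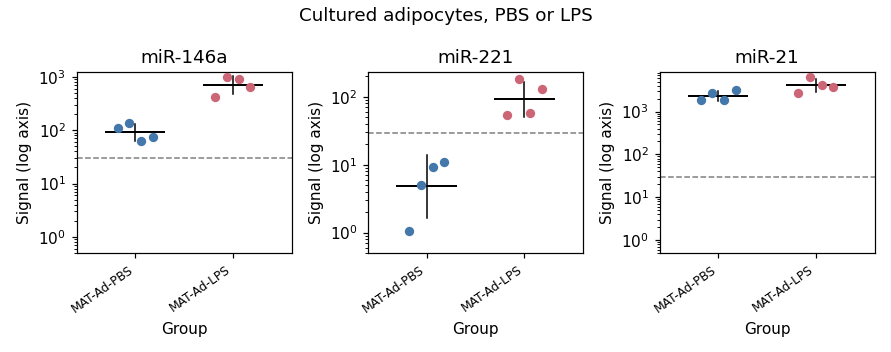
Signal (log axis) of miR-146a, miR-221 and miR-21 in cultured adipocytes given PBS or LPS; points are samples (4 per group), horizontal bars geometric means, vertical bars 1 SD of the log values and the dashed line the detection limit of 29.8. For miR-146a and miR-221 all LPS samples lie above all PBS samples, and for miR-21 the groups overlap.

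Exosomes from LPS-treated adipocytes carried more miRNA signal than those from PBS-treated ones. Of 26 miRNAs tested 8 passed, all higher: miR-21, miR-23a, miR-148a, miR-130a, miR-22, miR-25, miR-152 and miR-423-5p. miR-21, a miRNA found in many cell types and in blood plasma, went from 3.17 ± 1.82 to 799 ± 608 (SD, n = 3 each), at least 16.5-fold higher, as its PBS values were all below the detection limit. miR-148a, which rises in adipogenesis, was at least 11.9-fold higher, miR-25 at least 6.49-fold, miR-130a at least 5.08-fold, miR-152 at least 3.43-fold and miR-423-5p at least 2.36-fold. miR-22 was over the limit in all 6 samples, at 82.6 ± 39.1 and 4742 ± 5091. It read 58.8 in PBS replicate 1, where the ligation control was far lower, so its PBS values may include signal that needs no ligated miRNA. Limma adjusted p lay between 0.027 and 0.031. miR-146a stayed below the limit in PBS exosomes, at 10.1 ± 2.78, and had 36.1 ± 18.3 in LPS exosomes, and was not among the tested miRNAs.

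All 26 had a higher mean log2 value after LPS, with a median difference of 1.90 when miRNAs below the limit in 1 group were set to their bound. The filter chose many of them through the LPS group, which partly sets this outcome. Of 13 miRNAs over the limit in PBS exosome replicates 2 and 3, 10 were higher after LPS. Their median log2 difference from these 2 replicates was 0.596. Of the 13, let-7f (0.327), miR-142-5p (0.609), miR-200b (0.437), miR-202-5p (0.327) and miR-22 (4.76) were also over the limit in PBS replicate 1. The ligation control was far lower there, so their signal may not need ligated miRNA. The median over the 13 therefore need not measure the yield. None of the 4 lists passed the set test (lowest adjusted p = 0.16). The count was 0 without any 1 of the other 5 samples and 23 without LPS replicate 3, which had the lowest total of the 3. It was 0 after centring on the median or quantile normalization, and 3, all higher, after top-100 scaling.

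**Figure D4:**
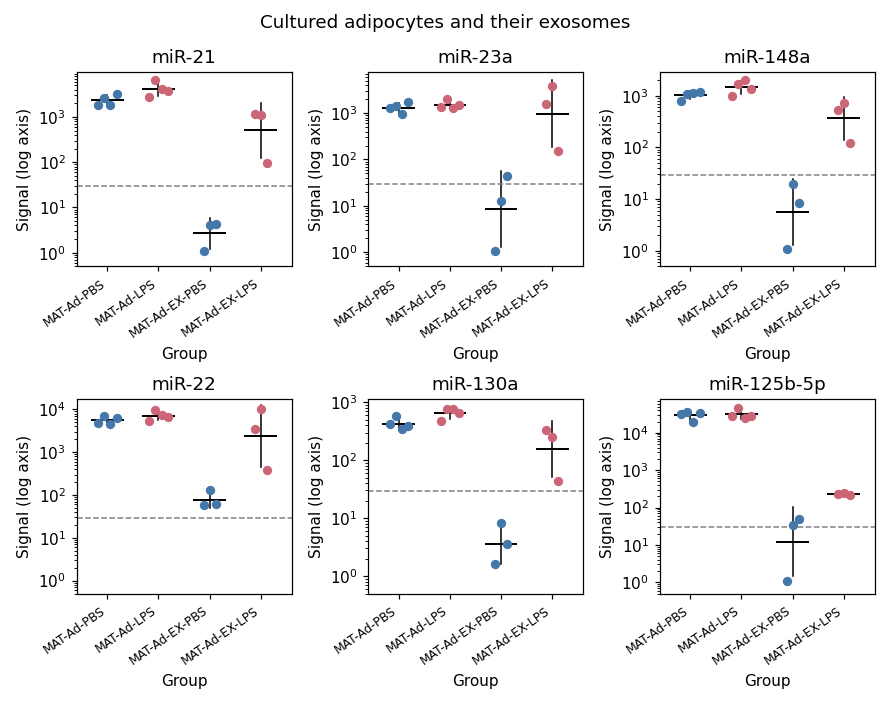
Signal (log axis) of 6 miRNAs in cultured adipocytes and their exosomes after PBS or LPS; points are samples, horizontal bars geometric means, vertical bars 1 SD of the log values and the dashed line the detection limit of 29.8. LPS exosomes lie above PBS exosomes for each miRNA shown, and miR-125b-5p, the most abundant in the cells, lies far lower in both exosome groups than in the cells.

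The fitted LPS effect was larger in exosomes than in the cells for 16 of 114 miRNAs and smaller for 1, among them miR-23a, miR-21, the smooth muscle miRNA miR-145 and miR-27a, with adjusted p from 0.0067 to 0.028. Most of these were below the detection limit in PBS exosomes, so sizes and their order are not measured. With values under the limit set to it 6 passed, and of the 17 only miR-22 (log2 difference of differences 4.61 ± 1.12 SE), miR-23a (4.59 ± 1.09), miR-148a (3.08 ± 0.68) and miR-125b-5p (2.53 ± 0.39) did. In cells miR-145 had means of 2041 ± 475 and 2286 ± 1422, whereas in exosomes it was at the floor in all 3 PBS samples and over the limit in 2 of 3 LPS samples. miR-19a, of the miR-17-92 cluster, was the one with the smaller effect: its LPS cells had 42.1 ± 29.6 and all other values were below the limit. miR-146a (-1.33 ± 0.69, adjusted p = 0.24, and -2.54, adjusted p = 0.0089, with values set to the limit) and miR-132 (1.37 ± 0.89, adjusted p = 0.34) did not pass, and the sign of miR-132 turned after centring on the median and with values set to the limit. None of 16 lists passed (lowest adjusted p = 0.12).

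The count was 43 without LPS exosome replicate 3. It was 9 without LPS adipocyte replicate 3 or 4, 10 without LPS adipocyte replicate 2 or PBS adipocyte replicate 2 or 4, and 11 without LPS adipocyte replicate 1. miR-27a lost its call without any 1 of these 6, PBS exosome replicate 2 or 3 or LPS exosome replicate 1 or 2 (adjusted p = 0.051 to 0.065). let-7b lost it without any 1 of the 8 adipocyte samples or PBS exosome replicate 1 or 2 (up to 0.078), and miR-199a-3p without any of these 10 or LPS exosome replicate 1 (up to 0.078). Centring on the median gave 5 higher and 30 lower, quantile normalization 2 and 5, and top-100 scaling 10 and 5. These scalings also rest on PBS exosome values mostly under the limit.

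Exosomes held far less signal than their cells. After PBS, 90 of 114 miRNAs were lower in exosomes and none higher. The growth-linked miR-125b-5p, the most abundant miRNA of the cells, was 30482 ± 7277 in PBS cells (n = 4) and 28.3 ± 24.6 in PBS exosomes (n = 3; adjusted p = 8.0e-08). miR-1944 was at least 187-fold lower, miR-29a, which targets collagens, at least 148-fold, let-7i at least 119-fold and miR-21 at least 76.0-fold. The smooth muscle miRNA miR-145 was at least 64.9-fold lower and miR-143 at least 22.9-fold. Like other miRNAs of the 114, the Sfmbt2 cluster did not pass: none of 3 tested members did, also adjusted over the list alone. Its miR-466g had 188 ± 162 in exosomes and 198 ± 37.8 in cells. The cluster passed the set test upward relative to other miRNAs (camera adjusted p = 0.045, and adjusted p = 0.86 with an estimated correlation). Its median and mean differences were below 0. Its 3 members turned higher in exosomes after centring, quantile normalization or top-100 scaling, which rest on PBS exosome values mostly under the limit. They also changed sign without PBS exosome replicate 1, whose ligation control was low.

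After LPS, 80 of 114 miRNAs were lower in exosomes and 3 higher. miR-125b-5p was 32281 ± 9703 in cells and 231 ± 18.5 in exosomes, 135-fold lower (adjusted p = 5.8e-06). miR-29b was at least 61.2-fold lower, miR-125a-5p at least 60.4-fold and let-7e at least 23.3-fold, and 9 of 9 let-7 family members tested fell short of the cells (9 adjusted over the list alone). miR-2183 was at least 2.08-fold higher, miR-1224 3.38-fold and miR-423-5p 2.20-fold, the last with the 3 of 4 cell samples below the limit set to it; their limma adjusted p were 0.038, 0.042 and 0.046. The call of miR-2183 was lost without LPS adipocyte replicate 1 or 2 or LPS exosome replicate 1 or 3 (adjusted p up to 0.14). That of miR-423-5p was lost without PBS adipocyte replicate 1, 2 or 4, LPS adipocyte replicate 1 or 3, PBS exosome replicate 3 or LPS exosome replicate 1 or 2 (up to 0.14). That of miR-1224 was lost without PBS adipocyte replicate 1, 2 or 3, LPS adipocyte replicate 1 or 2, PBS exosome replicate 3 or LPS exosome replicate 2 or 3 (up to 0.18). No list passed (16 tested, lowest adjusted p = 0.13).

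Scaling moved both splits, but PBS exosomes had only 7 to 14 probes over the limit. Their median, and most of the values scaled on, thus lay under the limit. Calls of higher miRNAs for PBS after scaling therefore need not mean more miRNA in exosomes. For PBS, centring on the median gave 39 higher and 23 lower, quantile normalization 32 and 33, and top-100 scaling 24 and 37; for LPS they gave 23 and 34, 21 and 27, and 24 and 32. Exosome RNA came from another extraction kit and carries another description letter than cell RNA, so exosome and kit cannot be told apart.

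Cultured PBS adipocytes were compared with chow MAT to describe what the culture lacks. Some markers of endothelium and blood were below the detection limit in all 4 cultures, while miR-23a, miR-29a and miR-16 of the same lists were over it in all 4. The endothelial miR-126-3p, 18153 ± 3217 in tissue (n = 5), was at least 582-fold lower, miR-150 at least 307-fold, the red cell miR-451 at least 149-fold, miR-142-3p at least 90.5-fold and the myeloid miR-223 at least 44.7-fold. The muscle miRNA miR-1 was at least 20.0-fold lower. miR-143 and miR-145 stayed measurable, at 719 ± 161 and 2041 ± 475, which was 11.8-fold and 17.1-fold lower. Higher in culture were miR-210, at 218 ± 43.9 against 62.4 ± 11.4, miR-132, at 338 ± 68.7 against 166 ± 38.2, and miR-2133 and miR-1983, at least 2.19-fold and at least 1.70-fold.

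Of 151 miRNAs, 122 differed, 6 higher and 116 lower in culture, and none of 17 lists passed the set test (lowest adjusted p = 0.087). Centring on the median gave 42 higher and 71 lower, quantile normalization 65 and 54, and top-100 scaling 56 and 55, and tissue and culture carry different description letters.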

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

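The tests of scaling, blood cells, ligation, cell carry-over, overall yield and the 2 near-constant probes, the paired permutation of B2m, and the counts of other splits, were chosen or written down only after the results they bear on had been seen.

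Of these, 5 were rewritten with new bounds after their first form had given its answer, since the first form rested on values under the limit, on miRNAs the filter had picked or on lost calls alone. For scaling the first bound asked for a lowest log2 difference above 2, which the fitted 2.99 met and the 0.693 given below would not have met; the new bound asks for more than 2 SE above 0. For the other 19 miRNAs the first form counted calls alone and went with scaling as the cause; the new form also asks how far the differences fell. The first blood cell test took the fitted values of all 4 miRNAs and argued against blood cells for all 4. The first ligation test asked for a fitted median above 2 without the sample. A second compared the median with and without the sample, values under the limit set to it, and was dropped: 6 of the 8 miRNAs were below the limit in all PBS exosomes, so it could hardly have moved. The first yield test counted 26 of 26 tested miRNAs higher and went with a higher yield, an outcome partly set by the filter.

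The first pattern is the rise of miR-221, miR-222, miR-335-3p and miR-335-5p in fat after HFD. Scaling is argued against for these 4: with values under the limit set to it, their lowest log2 difference under 5 other scalings was 0.693, and 0.356 less 2 SE. It stays open for the other 19 miRNAs called higher: all 19 stayed higher under all 5 and 8 stayed called. The median log2 difference of the 11 others went from 1.10 (median SE 0.252) to 0.880 (0.242) after centring. It was 0.627 (0.262) after quantile normalization and 0.801 (0.218) after top-100 scaling. The median difference thus shrank in these scalings, and why each call ended was not tested. A larger share of the blood cells already in the tissue is argued against for miR-221 and miR-335-5p, as far as the tested list members mark these cells. The 14 tested members of the white and red blood cell lists had a median log2 difference of 0.193 (robust SD 0.538). The highest, miR-342-3p, had 1.26, against 3.30 or more for the 2 with values under the limit set to it. Members such as miR-29a and miR-16 were also over the limit in culture, so the median says little about any 1 blood cell type. A blood cell type that no member marks was not tested. The explanation stays open for miR-222 and miR-335-3p, whose smaller value of 1.01 lies under that median plus 2 SD, 1.27. The diet remains an open, untested biological explanation, and a cell type newly entering the fat with its own content was not tested.

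The second pattern is the rise of 8 miRNAs in exosomes after LPS. Failed ligation in PBS exosome replicate 1 stays undecided as the cause. PBS replicates 2 and 3 lay below every LPS sample for all 8. Their ligation controls were 11843 and 10511, against 2832 in LPS replicate 2. With values under the limit set to it, the median log2 difference was 3.14 (median SE 1.14). The 8 were picked for a difference in these same samples, which largely set that outcome, so it cannot decide. None of the 8 passed without replicate 1. Whole-cell RNA carried over is argued against by the 4 mRNA probes, none of which was over the limit in any exosome sample. Actb had means of 2.99 ± 3.30 in LPS exosomes and 17293 ± 6115 in LPS cells. The 8 miRNAs were over the limit in all 3 LPS exosome samples. Whether the exosome kit recovers mRNA was not tested, so carry-over of small RNA alone stays undecided. Relative to miR-125b-5p, the 8 stood above their ratio in LPS cells by a median log2 of 6.09, 6.73 and 3.66 in the 3 samples. But the 8 were picked for high values in these samples, and miR-125b-5p lay further below the cells than most miRNAs. Over all 114 tested after LPS, the median log2 difference of exosomes from cells was -3.44. The kit also differs, so the ratio to miR-125b-5p cannot decide. More exosome RNA as a whole may account for part of it and stays undecided. Of 13 miRNAs over the limit in PBS exosome replicates 2 and 3, 10 were higher after LPS. Their log2 differences ran from -0.534 to 4.76. Some of the 13, among them let-7f and miR-142-5p, were also over the limit in the low-ligation replicate 1 and may not report yield. Centring took the median of the 8 from 4.99 (median SE 1.14) to 1.33 (median SE 1.18), so their calls ended because the difference shrank. That shrinkage was partly built in, as centring removes the shift shared by the 26 tested miRNAs. All 26 were higher after LPS, and many were picked through the LPS group. The shrinkage therefore does not favour a higher yield. Whether LPS raised vesicle release, vesicle loading or only the RNA put into the assay stays open.

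The third pattern is 2 probes, miR-142-5p and miR-200b, that lay over the limit in all samples and within 6-fold across the 29 other than PBS exosome replicate 1. Signal that needs no ligated miRNA may account for them: in that sample, where the ligation control was 0.0106 of the median of the other 5 exosome samples, the lower of the 2 still stood at 1.09 of its median there. The test first covered all 8 probes over the limit in the 29 samples, of which 5 fell to under 0.2 of their median and let-7f stood at 0.895; it was narrowed to the 2 near-constant probes after these values were seen. White blood cell RNA is argued against for miR-142-5p in culture, as it read 202 to 424 in the 8 cell samples while its other arm miR-142-3p reached at most 1.56. No biological explanation was tested.

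The LPS effect differed between exosomes and cells for 17 miRNAs. The fitted log2 differences of differences rest mostly on values under the limit, and with these set to it miR-22, miR-23a, miR-148a and miR-125b-5p of the 17 passed. The 17 fitted values are miR-23a 6.26, miR-21 6.23, miR-145 6.09, miR-27a 5.94, miR-148a 5.14, miR-25 4.77, miR-199a-3p 4.73, miR-22 4.61, miR-130a 4.41, let-7b 4.09, miR-210 3.96, miR-125b-5p 3.82, miR-152 3.70, miR-30a 3.21, miR-185 2.46, miR-125a-5p 2.07 and miR-19a -3.33. Of the runs without 1 sample, let-7b, miR-27a and miR-125b-5p passed in 4 of 14, miR-199a-3p in 3, miR-185 and miR-30a in 2 and miR-125a-5p in 7, and the others in every run that tested them. For the diet effect between aorta and fat the fitted values that passed are miR-222 (-4.59), miR-335-5p (-4.30) and miR-335-3p (-4.24). They restate the rise in fat, since all but 1 of their aorta values were under the limit, and do not measure a difference between the tissues.

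Of 140 sets of replicate values in groups of 4 or 5, 7 had a sample far from the others, where chance flags about 1 in 20. MAT-NCD replicate 3 had 142 probes over the limit (others 155 to 160). MAT-HFD replicate 1 had miR-221 at 212 (others 364 to 430). MAT-Ad-PBS replicate 3 had miR-125b-5p at 19734 (others 32505 to 35622), and MAT-Ad-PBS replicate 4 had miR-2133 at 191 (others 42.2 to 50.3). MAT-Ad-LPS replicate 2 had miR-100 at 685 (others 309 to 336) and miR-145 at 4412 (others 1439 to 1716), and MAT-Ad-LPS replicate 1 had 82 probes over the limit (others 107 to 111).

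Among the mRNA probes, which no comparison used, B2m, a component of MHC class I, was higher in LPS than in PBS adipocytes, at 1324 ± 431 against 669 ± 63.6 (log2 difference 0.937, n = 4 each; two-sided exact permutation p = 0.0286, or 0.15 adjusted over 16 tests, and 0.125 when only the signs of the 4 same-numbered pairs are turned, the smallest that pairing allows), with all 4 LPS samples above all 4 PBS samples. In fat B2m had 8193 ± 1289 after HFD and 5223 ± 1368 on chow (exact permutation p = 0.0159, 0.15 adjusted), and the ribosomal Rpl19 went the other way, at 1774 ± 285 and 2203 ± 195 (exact permutation p = 0.0238, 0.15 adjusted).

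Other splits of the same samples give a measure of chance. Among the splits run, only the real one gave as many calls for MAT diet (1 of 100, 24 calls, highest other 20). The same held for the diet effect between aorta and fat (1 of 100, 3 calls, which restate the rise in fat, highest other 1). It held for aorta against fat (1 of 56, 128 calls, highest other 31) and fat against culture (1 of 100, 122 calls, highest other 113). It held too for exosomes against cells after PBS (1 of 35, 90 calls, highest other 86) and LPS (1 of 35, 83 calls, highest other 71). These shares lie under 0.05 but do not exclude chance, as some other splits came close and the replicates may be technical. For adipocyte LPS 3 of 35 splits gave as many as 2 calls, and the highest other gave 15, several times the real count, which points to a structure of the samples. The other 2 parted 2 and 0 of the 4 same-numbered pairs, while the real split parts all 4. Among the 8 splits that part all 4, the blocked fit gave 8 calls for the real one and at most 1 for the others, and 8 splits are too few for a share under 0.05. Chance is likewise not excluded for the LPS effect between exosomes and cells, where 9 of 100 gave as many as 17 and the highest other gave 33. For AA diet (0 calls, as many in 10 of 10 splits, highest other 6) and exosome LPS (8 calls, 1 of 10 splits, highest other 0), 10 splits are too few for a share under 0.05.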

How the results depend on the processing

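Of 3810 values of named miRNAs under other settings, 3390 kept direction and side of the threshold, 342 lost the call, 48 gained one and 30 changed sign. Undoing the authors' factor, scaling to the positive controls, setting values under the limit to the limit, the block across sample kinds and leaving out doubted samples were chosen after seeing the data. Where a change follows from fewer samples or more miRNAs tested this is by construction; otherwise the cause was not tested. MAT diet gave 24 calls, but 13 with no filter, 62 with sample weights, 10 with all 30 samples in 1 fit, 54 with the authors' factor undone and 15 without HFD replicate 2 and chow replicate 5 together. Adipocyte LPS gave 2, but 1 with the limit doubled, 5 after centring, 4 after quantile normalization and 5 with positive control scaling. Exosome LPS gave 8, but 0 with no filter, after centring or after quantile normalization, 5 with the limit doubled, 3 after top-100 scaling, 17 with all 30 samples and 1 without PBS exosome replicate 1 and the probes over the limit in it. Exosome against adipocyte after LPS gave 83, but 48 after quantile normalization. The LPS effect between exosomes and cells gave 17, but 10 with a pseudocount of 16, 5 with no filter, 35 after centring, 7 after quantile normalization, 34 with sample weights, 32 with all 30 samples, 10 with the factor undone, 11 with positive control scaling and 6 with values set to the limit. The diet effect between aorta and MAT gave 3, but 5 with no filter and 8 with sample weights. With values set to the limit it also gave 3, without miR-222 (adjusted p = 0.15) and with miR-221, but where all aorta values are under the limit this sets the aorta effect to 0. The sample weights did not converge in the 4 comparisons with exosomes. AA diet gave 0 under every planned and added setting that kept all samples, and no other count of calls moved by over 1.5 times.

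With the number as a replicate block, adipocyte LPS gave 8 calls, MAT diet 8 and exosome LPS 0. The last 2 are not paired: same-numbered deviations correlated at -0.63 to 0.27 in MAT and -0.43 to 0.36 in exosomes, and at -0.23 to 0.10 in aorta, and 0 of 5, 1 of 3 and 1 of 3 samples correlated best with their own number. Across sample kinds, same-numbered exosomes and cells correlated at -0.24 to -0.013 after PBS and 0.012 to 0.22 after LPS, fat and culture at -0.23 to 0.25, and aorta and fat at -0.14 to 0.0068 on chow and 0.16 to 0.33 after HFD, where 3 of 3 correlated best with their own number. A block across kinds gave 90 and 84 calls for exosome against adipocyte after PBS and LPS, 18 for the LPS effect between them, 3 for the diet effect between aorta and MAT and 128 for aorta against MAT, and changed no call of a named miRNA. The block changed no other count of calls by over 1.5 times.

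Leaving out 1 sample gave 8 to 48 calls for MAT diet, 0 to 1 for AA diet, 2 to 4 for adipocyte LPS, 0 to 23 for exosome LPS, 86 to 92 for exosome against adipocyte after PBS and 70 to 92 after LPS, 9 to 43 for the LPS effect between them, 3 to 7 for the diet effect between aorta and MAT, 120 to 131 for aorta against MAT and 117 to 133 for MAT against culture.

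Of the miRNA lists, MAT diet had 5 passing, but 0 with an estimated correlation and 1 with the limit doubled. AA diet had 1, but 0 with an estimated correlation or after centring. Exosome against adipocyte after PBS had 1, but 0 with an estimated correlation or the limit doubled and 3 after centring. The diet effect between aorta and MAT had 3, but 0 with an estimated correlation. MAT against culture had 0, but 2 after centring and 1 with the limit doubled.

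Sign changes, in log2 difference, were as follows. For miR-132, adipocyte LPS gave -0.30 after quantile normalization and -0.0059 after top-100 scaling. In exosome against adipocyte after PBS, miR-466g, miR-467f and miR-669j were 3.51, 4.54 and 5.29 after centring, 3.84, 4.01 and 5.32 after quantile normalization and 2.74, 3.64 and 4.60 after top-100 scaling. With sample weights miR-466g was 0.023 and miR-467f 0.45. Without PBS exosome replicate 1, with or without its probes, miR-466g was 0.52, miR-467f 0.57 and miR-669j 0.00055. miR-669j was 0.12 without PBS exosome replicate 2 and 0.20 with the factor undone. Over all runs without 1 sample, miR-466g ranged from -3.05 to 0.52, miR-467f from -1.59 to 0.57 and miR-669j from -0.31 to 0.12. In the LPS effect between exosomes and cells, miR-146b was -0.998 after centring, -1.10 after quantile normalization and -0.046 after top-100 scaling, and miR-132 was -1.15 after centring and -0.34 with values set to the limit. In the diet effect between aorta and MAT, miR-142-3p was 0.24 with a pseudocount of 16, 0.25 with sample weights and 0.69 with values set to the limit. In MAT against culture, miR-133a was 0.078 after quantile normalization. PBS exosomes had 7 to 14 probes over the limit, which limits the exosome comparisons.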

Other observations

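The leading miRNA by mean share was miR-145 in fat and aorta, miR-125b-5p in cells, miR-142-5p in PBS exosomes and miR-22 in LPS exosomes. For miR-142-5p, at 9.06% ± 4.71 (n = 3), the signal may need no ligated miRNA, as given for the third pattern. It need not mean that PBS exosomes carry miR-142-5p. In fat miR-145 made up 11.9% ± 5.39 on chow and 10.6% ± 5.88 after HFD (n = 5 each). In HFD aorta the smooth muscle miRNA miR-145 made up 24.4% ± 1.06 of the miRNA signal (SD, n = 3), ahead of miR-720 at 10.8% ± 0.80 and miR-125b-5p at 10.5% ± 0.12. In PBS adipocytes miR-125b-5p made up 34.1% ± 4.53 (n = 4), followed by miR-1944 at 6.71% ± 1.64, miR-22 at 6.47% ± 0.62 and miR-29a at 5.20% ± 0.25. In LPS exosomes miR-22 led with 20.9% ± 12.5 (n = 3), followed by miR-23a at 8.35% ± 4.92 and miR-21 at 4.49% ± 3.51.

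One hypothesis was written before its test: that the miRNA content of LPS exosomes follows that of the cells. Across 100 miRNAs over the limit in either group, Spearman's rho of the group means was 0.49, between the 0.5 set for it and the 0.3 set against it, so the test leaves the hypothesis open. The miRNAs are not independent replicates, and the extraction kit differs between exosomes and cells.

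The mRNA of Actb, the cytoskeletal actin gene, read 10700 to 25020 in the 8 cell samples and at most 22.1 in the 6 exosome samples.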
